A study of Arabidopsis thaliana with 4 samples.

How the data were processed

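Chromatin was prepared from Arabidopsis thaliana Col-0 seedlings of 22 days, control or cold-treated for 2 h at 4 °C, fixed with formaldehyde, sheared to about 500 bp and precipitated with an antibody to AtHMGB15, per the labels' protocols. ChIP DNA was labelled with Cy5 and input DNA with Cy3 on every array, so dyes were not swapped and the enrichment of a probe is open to dye bias. The design has 2 groups of 2 arrays. The labels describe the input of the control arrays as from cold seedlings and that of the cold arrays as from control seedlings, which stayed unresolved, so a difference between inputs would enter cold minus control in either reading. Nothing in the labels says that replicates came from separate plantings, so p-values measure only the spread between these samples, which may be technical.

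The scanner files hold intensity values that the authors obtained with Agilent Feature Extraction 11.5.1.1, per the file headers. The processed intensity of each channel was background-subtracted, spatially detrended and dye-normalized, with linear dye normalization for replicate 1 of both groups and lowess for replicate 2, per the file headers. Dim spots carry a surrogate value, in 18.5%, 26.2%, 20.9% and 1.96% of probes of the ChIP channel of control 1, control 2, cold 1 and cold 2. The files also give a log10 ratio of Cy5 over Cy3, per the file headers, which was used only to check the direction. The authors' deposited value table holds log2 ratios whose normalization is not given in the sources used here. Its columns have medians of 0, -0.339, 0 and 0.0293 and correlate with the files' own log2 ratios at 0.78, 0.98, 0.78 and 0.96, which fixes the direction as Cy5 over Cy3. It is blank for 117595 probes of control 2 and 11825 of cold 2, of which 1.11% and 0.237% were well above background in ChIP. It served as an alternative.

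The main value is log2 of the processed Cy5 over the processed Cy3 signal, with outlier spots left out (60 to 188 per array) and each array centred on its median over probes, with no further loess or quantile step. A ratio of 0 therefore means the array's median probe, and an enrichment over the whole genome is not measured. The median net ChIP signal was 22.4, 2.98, 19.3 and 170 and the input signal 270, 193, 134 and 286 intensity units in the same order, and the SD of the ratio over probes 1.75, 2.41, 1.70 and 0.683. The number of arrays limits the precision.

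Probe positions and gene assignments are those of the array design on TAIR10, with a median spacing of 210 bp. Symbols and gene types came from a RefSeq gene table of TAIR10.1, in which 25767 of 25978 loci on the array were found and 10248 had a symbol of their own. Some symbols differ from common usage, and the locus decided. No genome sequence or strand was used here. The planned unit, a promoter of 1000 bp upstream of the transcription start, was therefore replaced by the gene flank: probes outside genes within 1000 bp of either end of the span of the gene's inside probes, averaged where there were at least 3. Of 78432 flank probes, 23461 flank more than 1 gene, so neighbouring genes share values. Exons, introns, untranslated regions and transposable elements were not told apart, and a promoter reaching 200 bp downstream was not run. GC content over 500 bp was taken as the mean over probes centred within that window.

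Flanks, gene bodies and probes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on group means over all 4 arrays, two-sided, Benjamini-Hochberg threshold 0.05). Gene lists, fixed before the data were examined along with the rules below, were tested with camera at a preset correlation of 0.01, adjusted over lists and comparisons, and again with an estimated correlation. fry, which tests whether a list's genes move on balance in 1 direction, gave adjusted p of at least 0.69 for every list. Bound regions were runs of at least 2 neighbouring probes, each within 1000 bp of the next, with a ratio of at least 1 on both arrays. Their chance number came from 100 circular shifts of one array's probe order against the other, a description and not a test of binding. Equal GC content and brightness means subtraction of the median of probes in the same GC and brightness class of that array.

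Genes named in the text were AT1G04880 first, then flanks past the threshold, of which there were none. For cold minus control they were the up to 5 largest differences per direction among protein-coding genes with a symbol whose arrays did not overlap, said not to pass. In each list they were the 2 to 4 members with the smallest p for cold minus control, with the number per list set after the data were seen. The genes at the 3 widest regions per group were named too.

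Both slides hold both groups. The replicate number marks the slide, per the file headers, and arrays with the same number deviated together from their group means (correlation 0.25 across flanks), so the replicate block is the slide block. It left 1 residual degree of freedom in place of 2. The fits were tested on simulated data with 200 features changed. Noise was independent, with the spread estimated in the fits and equal on all 4 arrays. The real arrays differed in the SD of the ratio (0.683 on cold 2, 2.41 on control 2) and varied together by slide. The shares recovered therefore do not measure the power of this design. Of changes of 4-fold and 8-fold between groups, 2.5% and 51.5% were recovered over 19732 flanks, and 0% of both over 414179 probes. Of enrichments of 4-fold and 8-fold in control, 37.5% and 96.5% were recovered over flanks and 0% and 0.5% over probes. The region rule found all the regions planted in simulated data of far lower noise than the arrays had. That checks the rule and does not measure its recovery on these arrays. Alternatives covered background correction (normexp, offset 50), loess on brightness, quantile and median absolute deviation scaling, and the authors' table. They also covered a filter to the 118317 probes well above background on all arrays, GC correction, the block, other flank definitions and each array left out. The normexp ratios started from raw mean signals and local background. They left out the scanner's dye normalization and spatial detrending, and so differ from the main values in more than background treatment.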

Results

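AtHMGB15, a plant nuclear protein that carries both an ARID and an HMG-box DNA-binding domain, was mapped on chromatin of Arabidopsis thaliana Col-0 seedlings 22 days old. Seedlings grown at 22 °C (control, 2 arrays) were compared with seedlings kept at 4 °C for 2 h (cold, 2 arrays), to find where the protein binds and whether binding differs after cold. Each tiling array measured DNA recovered with an AtHMGB15 antibody (ChIP, Cy5) against input DNA (Cy3) at 414565 probes, of which 257166 lay inside genes. The median net ChIP signal was 22.4 and 2.98 intensity units on control replicates 1 and 2, and 19.3 and 170 on cold replicates 1 and 2. The share of probes well above background in the ChIP channel was 61.3%, 40.2%, 57.8% and 95% in the same order, so that control replicate 2 was the dimmest array and cold replicate 2 by far the brightest. Replicate 1 of both groups shared a slide, and so did replicate 2 of both groups.

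At AT1G04880, the gene that encodes AtHMGB15 (chromosome 1, 1376191 to 1378980, TAIR10), the log2 ratio of ChIP over input averaged above 0 over the gene body in control, which did not pass the test for enrichment (limma adjusted p = 0.363). The mean log2 ratio over its 14 gene-body probes was 1.32 ± 0.57 in control and -0.07 ± 0.66 in cold (SD, n = 2 each). The last 3 probes were below 0 on both control arrays, and 8 of the 14 on control replicate 1. Within control, the first 6 probes of the gene formed one region of 1230 bp (1376191 to 1377420) with mean log2 ratios of 4.17 and 2.50 on replicates 1 and 2, against -0.60 and 0.50 on the cold arrays. The gene body ranked above 88.2% and 89.3% of 23559 gene bodies on the control arrays, and above 33.3% and 94.7% on cold replicates 1 and 2. The difference of cold minus control was -1.39 (SE 0.68), lower in cold on slide 1 (-1.46) and on slide 2 (-1.32), and did not pass the test across gene bodies (limma adjusted p = 0.999). Of the 7164 control regions 14 had at least 6 probes, and shifting one array's positions against the other gave 13.7 on average (5 to 21), no excess over chance. Only 2 probes lay in the flanks of this gene, too few for the flank test.

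**Figure D1:**
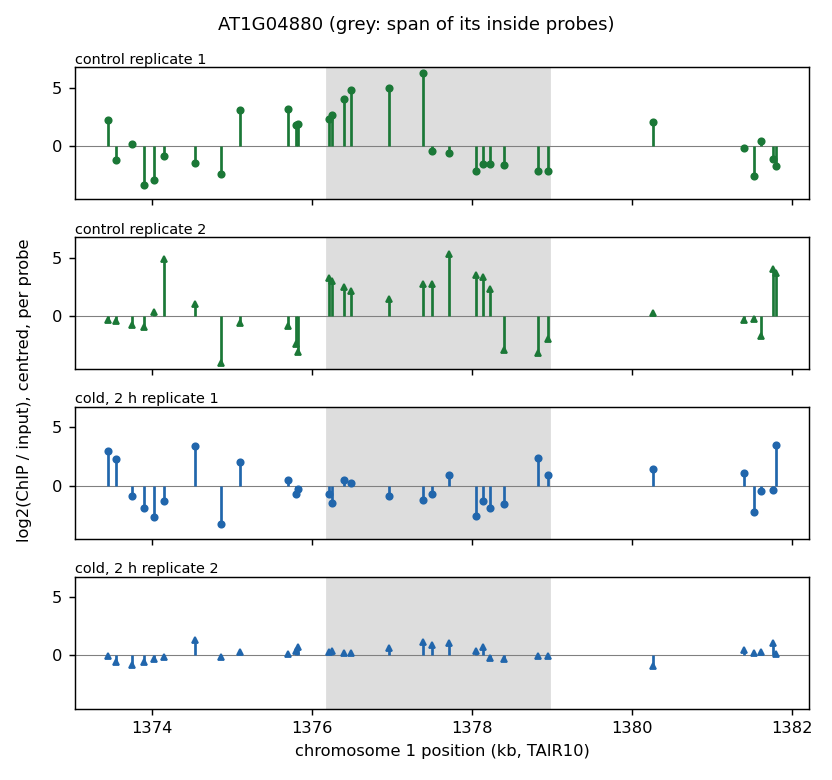
Log2 ratio of ChIP over input at each probe (vertical axis, centred on the array's median) against position on chromosome 1 (horizontal axis, kb, TAIR10) around AT1G04880, 1 panel per array; the grey band spans the gene's inside probes. On the control arrays 6 and 11 of the 14 gene-body probes exceeded 1, against 1 and 2 on the cold arrays. Of all probes, 33.5%, 31.3%, 32.3% and 4.93% reached 1 on control 1, control 2, cold 1 and cold 2. The cut was therefore far stricter on cold 2, and these counts cannot be compared with it directly.

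Where in the genome AtHMGB15 ChIP DNA lay was first described by probe class. On 3 of the 4 arrays, DNA flanking genes (within 1000 bp of either end) had higher ChIP over input than gene bodies. The median flank ratio exceeded the median body ratio by 1.07 (SE 0.011, from resampling 1 Mb bins) on control replicate 1, by 1.05 (SE 0.014) on cold replicate 1 and by 0.19 (SE 0.0092) on control replicate 2. On cold replicate 2 flanks lay below bodies, at -0.088 (SE 0.0047). The spread between cold replicates was thus as large as the difference itself. Farther intergenic probes had medians of 0.72, 0.14, 0.72 and 0.05 on control 1, control 2, cold 1 and cold 2, against -0.47, -0.10, -0.47 and 0.01 for gene bodies. Medians rose from inside genes outward on the slide 1 arrays, from -0.59 at 750 to 1000 bp inside the gene edge to 0.85 at 750 to 1000 bp outside on control replicate 1, and from -0.57 to 0.78 on cold replicate 1. Among probes of equal GC content and brightness, the flank excess shrank to 0.16, 0.049 and 0.11 on those 3 arrays and stayed negative (-0.086) on cold replicate 2. The excess also moved with the values used. Slide 1 arrays had linear and slide 2 arrays lowess dye normalization, so a difference between slides cannot be told apart from this step. After loess on brightness the excess was 0.36, 0.020 and 0.30 on control 1, control 2 and cold 1, and -0.105 on cold replicate 2. With normexp it was 1.27, 0.81 and 0.86 on control 1, control 2 and cold 1, and with the authors' values it was 0.19, 0.47 and 0.11, and it was negative on cold replicate 2 with both.

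**Figure D2:**
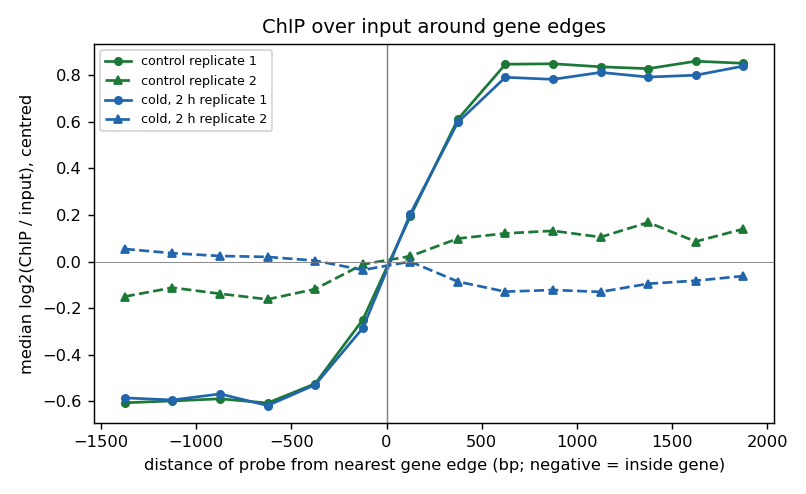
Median log2 ratio of ChIP over input (vertical axis, centred per array) in bins of 250 bp by distance from the nearest gene edge (horizontal axis, bp, negative inside genes). Solid lines with circles are slide 1 (replicate 1) and dashed lines with triangles slide 2 (replicate 2); green is control and blue is cold. The slide 1 lines run together from about -0.6 to above 0.8, while cold replicate 2 stays between -0.13 and 0.05.

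The probes with the highest 5% of mean ratios lay in classes close to their share of the array in control with the processed signals. In control 60.5% of them lay in gene bodies, 20.1% in flanks and 19.5% farther out, against 62.0%, 18.9% and 18.9% of all probes. Taken singly, control replicates 1 and 2 had 69.9% and 63.9% in gene bodies and 13.8% and 18.8% in flanks. With normexp background correction of the raw signals the control shares were 31.6%, 33.6% and 34.8%, so the statement depends on how the signals were processed. In cold the shares were 69.0%, 12.7% and 18.3%, but the cold arrays differed from each other more than the groups did, with 73.6% in gene bodies on replicate 1 and 44.3% on replicate 2. GC content of the probe had little monotonic relation to the ratio of processed signals. Across probes, which are not independent replicates, the Spearman correlation was -0.016 and 0.018 on the control arrays and -0.056 and -0.035 on the cold arrays. With normexp it was -0.42, -0.31, -0.40 and 0.055 on control 1, control 2, cold 1 and cold 2, and among probes well above background it was -0.24 on control 2. The relation bent at both ends. Probes under 25% GC had median ratios of 2.25, 0.42, 1.47 and 0.46 on control 1, control 2, cold 1 and cold 2, and probes of at least 50% GC had 0.92, 0.78, 0.52 and 0.058, whereas those of 35 to 40% GC lay below 0 on all 4 arrays. Fewer than 1% of the probes under 25% GC were well above background in ChIP on the slide 1 arrays (0.76% and 0.59%).

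The next question was which genes AtHMGB15 bound in each condition. No gene flank passed the test for enrichment over the array's median in control or in cold. limma with Benjamini-Hochberg adjustment called 0 of 19732 flanks in each group. At an unadjusted p under 0.05, 3527 flanks lay above 0 in control (smallest adjusted p = 0.102) and 92 in cold. These counts depend on the scaling, with 1811 and 1365 after quantile normalization and 1655 and 497 after scaling by the median absolute deviation. In either direction, 19.1% of flanks in control and 0.644% in cold had an unadjusted limma p under 0.05. A chance share of 5% does not apply here, since the test was against the median of all probes. The median flank lay above that, at 0.52 in control and 0.12 in cold, so the share in control restates in part the flank excess. The test used 1 spread for both groups, so the few calls in cold do not show that binding was absent. Of 414179 probes, 0 passed in either group, with 37803 in control and 1568 in cold at an unadjusted p under 0.05, an order that turned after quantile normalization (19533 and 24222). Of 23559 gene bodies, 0 passed, with 1859 and 91 at an unadjusted p under 0.05. The control result depended on how the signals were processed: with normexp in place of the scanner's processed signal, 5594 flanks passed in control and 0 in cold. The normexp ratios also lack the scanner's dye normalization and detrending, so the change cannot be credited to background treatment alone. Leaving out 1 array also gave calls in control, between 186 flanks without control replicate 2 and 2404 without control replicate 1, where the dim control replicate 2 stood alone.

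Bound regions were runs of at least 2 neighbouring probes with a log2 ratio of 1 or more on both arrays of a group. Control had 7164 such regions and cold had 651. With each array scaled by its median absolute deviation the counts were 5434 and 4942, so the gap depends on the scaling. Both counts were set against shifts of one array's positions along the genome, which keep each array's own clustering. In control the shifts gave 6956 regions on average (range 6758 to 7108 over 100 shifts), so the 7164 regions were 1.03 times that number, and 9166 regions met the same rule with the sign turned. With normexp control had 8141 regions against 3076 under shifts (2937 to 3179) and 9812 of opposite sign, and after a GC correction of the processed ratios 6617 against 5889. With a threshold of 0.5 control had 15565 regions against 13329 to 13753 under shifts, and 17427 of opposite sign. Control did not exceed the range of shifts with scaling by the median absolute deviation (5117 to 5463), with a threshold of 1.5 (3734 regions, 3582 to 3818) or with runs of 3 probes (1420 regions, 1346 to 1495). In cold the shifts gave 263.9 (226 to 314), 437 regions had the opposite sign, and the 651 regions were 2.47 times the shifted number. Control replicate 1 with cold replicate 2, a pair of different group and slide, had 718 regions, 2.49 times its shifted number, so the excess is not particular to cold. Cold regions were AT-rich, at 27.4% GC on average against 38.4% for all probes and 40.7% in control regions, and after a GC correction 159 cold regions stood against 129.7 in shifted data (102 to 155), with 302 of opposite sign. Of cold region probes 48.2% were farther intergenic, 31% in flanks and 20.7% in gene bodies. In control regions these shares were 20.8%, 18.7% and 60.5%. A total of 47 control regions overlapped a cold region, with 38.2 (20 to 56) under shifts, and 20 regions were called on all 4 arrays, with 15.6 (7 to 26) under shifts.

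The widest control regions lay on chromosome 3 at 4372111 to 4374510 (2400 bp, by AT3G13430 and AT3G13433), on chromosome 1 at 22166341 to 22168440 (2100 bp, between AT1G60095 and AT1G60110) and on chromosome 3 at 20115451 to 20117460 (2010 bp, inside WRI1). In the first 2 of these, 2 of 6 and 1 of 4 probes were well above background in both channels on both control arrays. WRI1, a transcription factor of seed oil synthesis, had mean log2 ratios of 2.98 and 2.90 on the control arrays over 5 probes, all well above background, against 1.34 and -0.63 on the cold arrays. The widest cold regions lay on chromosome 3 at 13257601 to 13259580 (1980 bp, with no gene named by the array), on chromosome 4 at 8130391 to 8132310 (1920 bp, by AT4G14104 and COP9, a gene of the COP9 signalosome) and on chromosome 2 at 6373801 to 6375360 (1560 bp, by AT2G14835). At none of these 3 cold regions was a probe well above background in both channels on both cold arrays, and the mean log2 ratio of control replicate 1 there was higher than that of either cold array (2.25, 2.12 and 2.34).

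**Figure D3:**
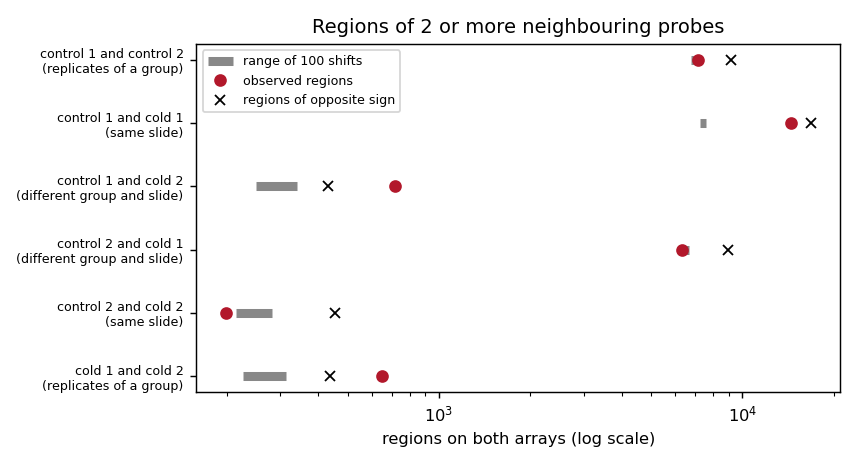
Number of regions called on both arrays of each pair (red circles, horizontal log axis), the same rule with the sign turned (crosses), and the range over 100 shifts of one array's positions (grey bars), for the 6 pairs of arrays (vertical axis). Control replicates share 7164 regions against at most 7108 under shifts, and the arrays of slide 1, one control and one cold, share 14434 against at most 7567.

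Binding after 2 h of cold was compared with control flank by flank. No flank passed: limma with Benjamini-Hochberg adjustment called 0 of 19732 flanks, 833 of them (4.22%) had an unadjusted p under 0.05 where chance gives 5%, and the smallest adjusted p was 0.994. The same test called 0 of 414179 probes (18687 at an unadjusted p under 0.05) and 0 of 23559 gene bodies (965). The median flank was 0.39 lower in cold on the log2 scale, and differences of single genes and lists are to be read against this shift. It ranged from -0.16 to -0.48 over the scalings tried, and was -0.63 without cold replicate 1 and -0.15 without cold replicate 2. Medians over flanks were 0.54, 0.38, 0.39 and -0.10 on control 1, control 2, cold 1 and cold 2. Most of the shift thus came from cold replicate 2. Both cold arrays lay beyond both control arrays at 32.7% of flanks, and chance gives 33.3%, but the directions were unequal. Cold was lower without overlap at 5215 flanks (26.4%) and higher at 1241 (6.29%), where chance gives 16.7% each. These chance shares hold for exchangeable arrays, whereas arrays of a slide varied together and cold replicate 2 lay lower over flanks as a whole. Within slides, 8688 flanks were lower in cold on both and 2557 higher on both. The differences of slide 1 and slide 2 had a Spearman correlation of 0.039 across flanks, which are not independent replicates.

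The flanks with the largest differences among genes with a symbol did not pass the test (all at limma adjusted p = 0.994). Among flanks whose arrays did not overlap, the largest positive differences were at RKD2, a transcription factor of egg cell identity, and PRXIIF, the mitochondrial peroxiredoxin. ARAD2, RABH1e, a Rab GTPase, and CPK33, a calcium-dependent protein kinase, came next. In this order, the differences of cold minus control were 3.21 (SE 1.12), 2.56 (SE 0.78), 2.35 (SE 0.76), 2.27 (SE 0.91) and 2.26 (SE 0.79). RKD2 had a mean log2 ratio of -1.75 ± 1.54 in control and 1.47 ± 2.78 in cold (SD, n = 2), ARAD2 -2.14 ± 0.71 and 0.21 ± 0.03. On control replicate 2 no probe of the RKD2, PRXIIF, RABH1e or CPK33 flanks was well above background in ChIP. The same held for GolS3, LFY, RVE1, JAR1 and RBCS1A among the genes of the lists, for AILP1, HMGB3, IAA14, AGL104 and AGL66 on cold replicate 1, for LHCB5 on control replicate 1 and for ABF3 on both slide 1 arrays. The largest negative differences were at CSR1, the acetolactate synthase of branched-chain amino acid synthesis, AILP1, and PDH-E1 ALPHA, a subunit of plastid pyruvate dehydrogenase. AIM1, an enzyme of fatty acid β-oxidation, and VTI13, a SNARE protein, came next. The differences in this order were -4.92 (SE 1.08), -4.00 (SE 1.43), -3.97 (SE 1.40), -3.88 (SE 0.84) and -3.87 (SE 1.18). AIM1 was high on both control arrays (4.00 and 3.53) and at 0.94 and -1.15 on the cold arrays, whereas AILP1, PDH-E1 ALPHA and VTI13 owed most of the difference to control replicate 2, at 5.83, 6.41 and 6.79 against -0.70, 0.27 and 1.94 on replicate 1. With normexp, 19 flanks passed, 11 higher and 8 lower in cold, among them RKD2 (1.94), PRXIIF (1.83), ARAD2 (2.67), CSR1 (-1.91) and AIM1 (-1.87). Without control replicate 1, 1132 flanks passed, 1102 of them lower in cold, and without control replicate 2, 5 passed. Of the 40 flanks named for the difference, here and among the gene lists, 31 moved by over 1.5 times or turned when some 1 array was left out. The 9 that did not were PRXIIF, ARAD2, AIM1, MYC3, LOX3, KNAT2, RBCS1A, AGL104 and HSP23.6-MITO.

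**Figure D4:**
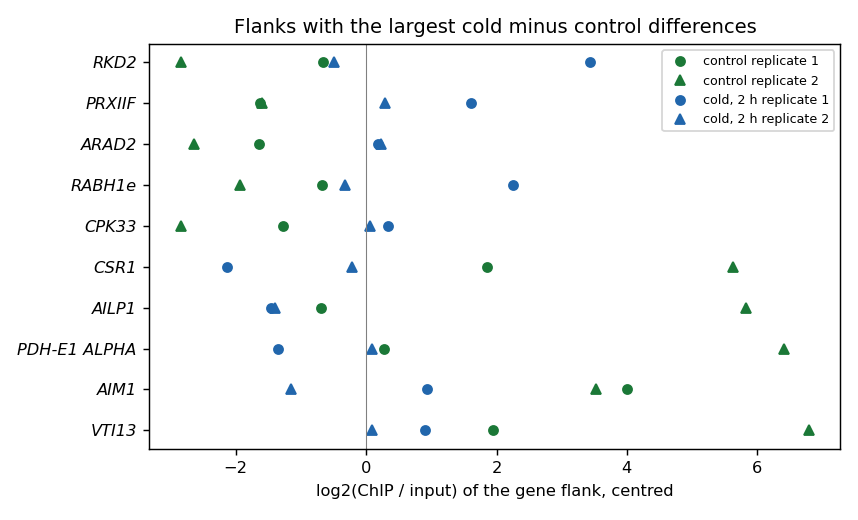
Log2 ratio of ChIP over input of the gene flank on each array (horizontal axis) for the 10 genes with a symbol and the largest differences whose cold and control arrays did not overlap (vertical axis); circles are replicate 1, triangles replicate 2, green control and blue cold. None passed the test, and the highest values, 5.63 to 6.79, are all of control replicate 2.

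Gene lists fixed in advance were then tested against all other flanks with camera, over 12 lists and 3 comparisons, so a direction is relative to other flanks and can differ from the sign of a median. No list differed between cold and control, in either direction, and no member of any list passed for the difference over all flanks or adjusted over the list alone. The 23 measured members of the cold response regulon, which takes in CBF transcription factors, regulators of cold response and cold-induced genes, had a median difference of -0.28, close to the -0.39 of all flanks (camera adjusted p = 0.94). ICE1, the upstream regulator of CBF3, had log2 ratios of 2.41 ± 0.41 in control and 0.19 ± 1.40 in cold (SD, n = 2; difference -2.23, SE 0.83). GolS3, which makes galactinol in the cold, had -1.26 ± 0.75 and 0.55 ± 1.47 (difference 1.81, SE 0.86). KIN1 and ADH1 had differences of -1.41 (SE 0.83) and -1.31 (SE 0.82), which went to -0.50 and -0.38 without cold replicate 2. The flanks of 5 members lay lower in cold on both arrays than on either control array and those of 1 member higher.

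The jasmonate list had a median difference of -0.61 over 25 genes (adjusted p = 0.85). MYC3, a transcription factor of the jasmonate response, had a log2 ratio of 1.70 ± 0.16 in control and -0.09 ± 0.28 in cold (difference -1.78, SE 0.74). LOX3 and JAR1, enzymes of jasmonate synthesis and conjugation, had differences of -1.44 (SE 0.75) and -1.43 (SE 0.86), and JAZ1, a repressor, -1.12 (SE 0.79). Of the 25 flanks, 11 were lower in cold without overlap of arrays and 1 higher, where 26.4% and 6.29% of all flanks were. The abscisic acid list stood at -0.79 over 20 genes (camera unadjusted p = 0.044 with limma, adjusted p = 0.77), with ABF3 at -2.19 (SE 0.84) and SNRK2.3 at -1.91 (SE 0.84). With the median of probes these 2 differences were -0.53 and -2.20. The auxin list stood at -0.46 over 19 genes, with IAA19 at -1.62 (SE 0.79) and IAA14 at -1.29 (SE 0.77).

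The circadian clock list in cold gave the only test that passed over the 12 lists and 3 comparisons. Its 8 measured flanks were lower than other flanks in cold (camera adjusted p = 0.042), a call lost with an estimated correlation (adjusted p = 0.98). They had a median of -0.56 over group means, against 0.14 in control. On the single cold arrays the median of the list was -0.31 and -0.13, where all flanks had 0.39 and -0.10, so on cold replicate 2 it lay near all flanks. The call was also lost with a GC correction (adjusted p = 0.50), with normexp (adjusted p = 0.21), without cold replicate 1 (adjusted p = 0.66) and without cold replicate 2 (adjusted p = 0.096), and held with the slide as a block (adjusted p = 0.029). CCA1, a morning transcription factor of the clock, had -1.06 ± 1.23 in cold and 0.53 ± 2.21 in control. PCL1 and ELF4, which act in the evening complex, had 1.29 ± 1.64 and 1.26 ± 1.17 in control and -0.57 ± 0.37 and 0.07 ± 0.11 in cold. With the median of probes the difference of cold minus control fell to -0.84 for PCL1 and turned from -1.18 to 0.083 for ELF4, and for CCA1 it was -0.023 without control replicate 2. RVE1 stood at -0.74 ± 0.57 in cold and 0.31 ± 0.51 in control. The difference of the list between cold and control did not pass (median -0.70, adjusted p = 0.85).

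The other lists had median differences between -0.43 and 0.083 and adjusted p of at least 0.77. Over 9 HMG-box genes the median was 0.083, with 3xHMG-box1 at -0.57 (SE 0.79) and HMGB3 at -0.51 (SE 0.77). 3xHMG-box1 turned to 0.18 without control replicate 2, and HMGB3 to 0.012 with quantile normalization and to 0.045 with the median of probes. Over 19 flowering time genes it was -0.31, with FRI at -1.42 (SE 0.86) and LFY at 1.22 (SE 0.83), a difference that turned to -0.045 with normexp. Over 14 photosynthesis genes it was -0.30, with LHCB5 at -2.02 (SE 1.36), which rested on control replicate 2 (1.02 without it), and RBCS1A at 1.03 (SE 0.74). Over 9 heat shock genes it was -0.29, with Hsp70b at -1.06 (SE 0.76) and HSP23.6-MITO at -0.83 (SE 0.74). Over 13 genes of pollen and the pollen tube it was -0.18, with AGL104 at -1.20 (SE 0.75) and AGL66 at -0.68 (SE 0.75), which turned to 0.29 with the median of probes. The 14 constitutively expressed reference genes stood at -0.43, with UBC9 at -2.17 (SE 0.93), or -0.64 without control replicate 2, and ROC1 at -1.58 (SE 0.77). The 14 silent developmental regulators stood at -0.28, with SEP1 at -2.73 (SE 1.18), or -0.65 without control replicate 2, and KNAT2 at -1.24 (SE 0.74). In control, 2 abscisic acid, 2 reference and 1 cold regulon flanks were above 0 when adjusted over the list alone, and none over all flanks.

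How far replicate arrays matched was compared last. The log2 ratios of the control replicates had a Spearman correlation of 0.16 across probes and those of the cold replicates 0.032. The control and cold arrays of slide 1 correlated at 0.38, and those of slide 2 at 0.058. With normexp the control replicates correlated at 0.35, the cold replicates at -0.0031, the slide 1 arrays at 0.49 and control replicate 2 with cold replicate 1 at 0.30. Neighbouring probes 100 to 300 bp apart correlated at 0.33, 0.27, 0.29 and 0.24 within control 1, control 2, cold 1 and cold 2, but at 0.034 and -0.0073 between control replicates and between cold replicates. Across flanks the control replicates correlated at 0.12, the cold replicates at 0.019 and the slide 1 arrays at 0.54. Probes and flanks are not independent replicates, and these 6 pairs share arrays.

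**Figure D5:**
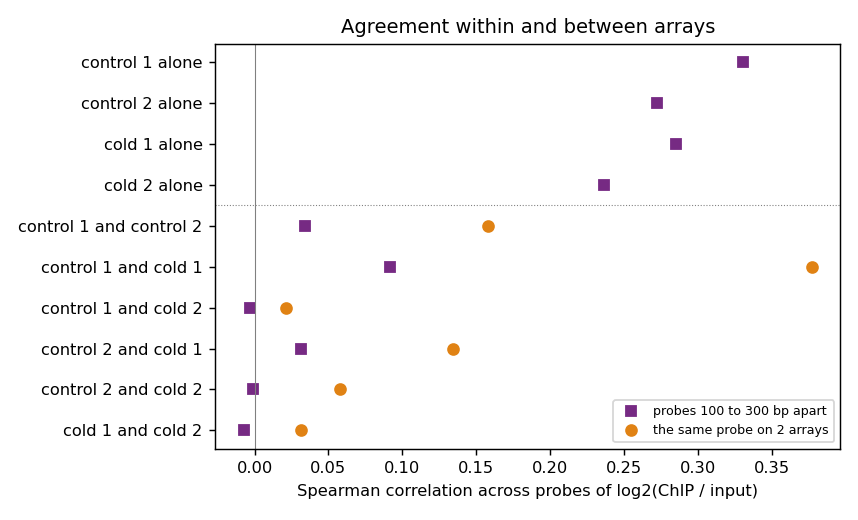
Spearman correlation across probes of the log2 ratio (horizontal axis) between probes 100 to 300 bp apart (purple squares) and of the same probe on a pair of arrays (orange circles), for each array alone and for each pair (vertical axis). Neighbours correlate by 0.24 to 0.33 within arrays and by -0.0073 to 0.092 between arrays.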

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

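Tests that paired the block with normexp or quantile normalization, the values limited to probes named for the gene, and the alternatives for the flank minus body difference and the organelle medians were chosen after the data were seen. The counts of 0 flanks and 0 probes stayed at 0 with loess, MAD scaling, the authors' table, the well-above-background filter (653 flanks left), GC correction, flanks of 500 bp, a minimum of 1 probe, gene bodies, probes named for the gene and, for the difference, each channel alone. The replicate block, which is the slide block, gave 0 calls for flanks and probes in control, cold and the difference (4285, 258 and 1047 flanks at an unadjusted p under 0.05), also with GC correction (0), and changed no list call. Flanks enriched in control numbered 5594 with normexp, 7650 with normexp and the block, 163 with quantile normalization and the block, and 200 with the median of probes. In cold they numbered 185 with quantile normalization and the block and 1 with normexp and the block. Changed flanks numbered 19 with normexp, 72 with normexp and the block, and 8 with quantile normalization and the block. Leaving out 1 array in turn, with the lone array assumed to vary like the other group, gave 186 to 2404 flanks enriched in control and 1 to 1132 changed, and 0 to 42899 probes enriched in control and 0 to 28202 changed. Each highest count came without control replicate 1.

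Regions at thresholds of 0.5 and 1.5 numbered 15565 and 3734 in control, 5005 and 8 in cold and 1364 and 1 shared. With a run of 3 probes they numbered 1420, 51 and 0. In cold they numbered 98 with normexp, 159 with GC correction and 4942 with MAD scaling, and shared regions 1, 17 and 322, or 20 at 50% overlap. With 1 array alone, control had 31788 to 33895, cold 1697 to 32971, and 119 to 3140 were shared. The number of list calls, 1, became 0 with an estimated correlation, normexp, GC correction or gene bodies, and was 0 to 1 without 1 array; without cold replicate 1 it was the cold response regulon in cold, lower than other flanks (adjusted p = 0.034). With normexp the top probes of control lay 31.6% in gene bodies, 33.6% in flanks and 34.8% farther out. Without 1 array these shares were 63.9 to 69.9%, 13.8 to 18.8% and 16.2 to 17.3% in control, and 44.3 to 73.6%, 11.4 to 25.6% and 15.0 to 30.2% in cold. The mean correlation with GC content, 0.00065 in control and -0.045 in cold, became -0.367 and -0.174 with normexp and -0.058 and -0.028 over 500 bp, and ranged from -0.016 to 0.018 without 1 control array. Of 550 values of 40 named flanks under other settings, 543 kept their direction and 13 passed the threshold. Without 1 array, 158 of 160 kept their direction. These counts do not measure robustness. The block leaves the difference of this balanced design unchanged. A flank whose arrays do not overlap cannot turn when 1 array is left out, so many of these values could not turn. Those that turned were HMGB3 (0.012 with quantile normalization, with and without the block, and 0.045 with the median of probes), ELF4 (0.083) and AGL66 (0.29) with the median, LFY (-0.045 with normexp, with and without the block), and 3xHMG-box1 (-1.32 to 0.18) and LHCB5 (-5.05 to 1.02) over arrays left out. The mitochondrial medians of control 1 and cold 1 turned to -0.35 and -0.22 with normexp and to -0.88 and -0.64 in the authors' table. The planned promoter reaching 200 bp downstream was not run, for lack of strand. Apart from normexp, weighed under other observations, the cause was not tested. The ChIP channel was dimmest on control replicate 2, where 40.2% of probes were well above background.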

Other observations

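The tests of explanations and the alternatives for organelle medians in this part were chosen after the results were seen. Organelle DNA differed between arrays in ChIP over input. Chloroplast probes (256) had median log2 ratios of -0.49, -0.21 and -0.10 on control 1, control 2 and cold 1, and of -2.83 on cold 2, where 98.8% of them lay below 0. Mitochondrial probes (477) had 1.20, -0.035, 1.05 and -1.39 in the same order. With normexp the chloroplast medians were -1.83, -1.86, -1.23 and -1.94, and the mitochondrial medians -0.35, -1.49, -0.22 and -0.75, lowest on control 2 in place of cold 2. In the authors' value table the chloroplast medians were -2.43, -1.16, -1.55 and -2.70, so the order of arrays depends on the processing. Probes in the 25 of 121 nuclear bins of 1 Mb with fewest genes had medians of 0.31, 0.14, 0.35 and 0.17, above the other bins (-0.047, -0.021, -0.050 and -0.023) on all 4 arrays.

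The 20 regions found on all 4 arrays included stretches by MYB50 (chromosome 1, 21318481 to 21318840), CYP714A2, a gibberellin-inactivating enzyme (chromosome 5, 8564101 to 8564280), and RST1 (chromosome 3, 10247341 to 10247880). These genes were picked after their values were seen, and shifts gave 7 to 26 such regions.

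Within each array, neighbouring probes varied together, but replicates shared little of this pattern. Independent noise of single spots is argued against by a correlation between neighbours of at least 0.332 on every array among probes well above background. Dim signal stays open for the control replicates. Their correlation was 0.0642 among those probes and 0.158 over all, which goes against it, but with normexp and a GC correction it was 0.285 across flanks where the processed signals gave 0.122. That each ChIP sample was made from few DNA fragments drawn separately stays open. Neighbours on 1 array correlated by at least 0.238 more than neighbours on replicates and by at most 0.051 at 1000 to 5000 bp, but the first restates the pattern, and the slide 1 arrays shared ratios (0.377), which separate draws alone would not give. No biological explanation was tested, and the amount of ChIP DNA per sample is not given in the sources used here.

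The control and cold arrays of slide 1 shared their ratios (0.377) more than any replicates did. Matching probes on GC content and brightness left 0.452, with 0.205 for the control replicates, which argues against these probe properties as the whole cause. Binding common to control and cold seedlings stays open. The values against it come from both slide 2 arrays. Among probes well above background the dim control replicate 2 correlated with control replicate 1 at 0.0642 and with cold replicate 1 at 0.0606. With normexp these 2 pairs had 0.352 and 0.296, where the slide 1 arrays had 0.485, so control replicate 2 does not settle it. The other is the bright cold replicate 2, whose log2 ratios varied least (SD 0.683). Among probes well above background this array correlated with cold replicate 1 at 0.0247 and with control replicate 1 at -0.00055, where the slide 1 arrays had 0.307. On cold replicate 2 the ChIP and input signals had a Spearman correlation of 0.947 across probes, against 0.838, 0.539 and 0.845 on control 1, control 2 and cold 1. Whether the ChIP of cold replicate 2 enriched bound DNA was not tested. A batch of slide 1 stays open and cannot be told apart from what those samples share, since no other sample lies on slide 1.

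With normexp, 5594 flanks passed in control and with the processed signals 0. Taking the trend with GC content from the normexp ratios left 0 flanks: the median flank ratio in control went from 0.47 (median SE 0.31) to 0.23 (median SE 0.25), and the smallest adjusted p was 0.052. Many of the calls thus depended on the trend with GC content, but whether that trend is technical cannot be told. Flank probes had a median GC content of 33.3% and gene-body probes 40%, so the correction would also remove any binding to AT-rich DNA. After it, 3883 flanks still had an unadjusted limma p under 0.05, and control regions numbered 2046 against 1040 to 1194 under shifts. Binding at gene flanks in control stays open as a hypothesis. Flanks exceeded bodies on both control arrays at equal GC content and brightness, by at least 0.0491, but without a dye swap this cannot be told apart from a dye effect.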
